A study of Mus musculus with 6 samples.

How the data were processed

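The series holds nuclear RNA from HL-1 cells, a mouse cardiomyocyte line of atrial origin that keeps beating in culture. Per the labels' protocols, nuclei were released by detergent and separated biochemically into a chromatin pellet extract and a soluble nuclear extract, with 3 libraries from each fraction and 6 in all, described as biological replicates. ERCC spike-in standards, a set of synthetic RNAs, were added to every fraction ahead of the RNA extraction. The amount added per cell or per fraction is not given in the sources used here. Ribosomal RNA was depleted and strand-specific libraries were made, per the labels' protocols. HISAT2, SAMtools, Cufflinks, bedtools, Cuffdiff and the build mm10 are named in the submitters' processing notes. Their versions, settings and order are not given in the sources used here.

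The authors deposited 1 table for the whole series. Per the file headers, it gives 1 FPKM value (fragments normalised to transcript length and library size) per fraction for each locus, so the 3 replicates of a fraction stand pooled in a single value. It also holds a pellet signal rescaled by the authors, a total signal that adds the soluble FPKM to the rescaled pellet signal, and the ratio of the rescaled pellet to the soluble value as chromatin enrichment, per the file headers. The log10 of the total and the log10 of the ratio are deposited beside them. The rescaled pellet column was compared with the spike-ins: it equals pellet FPKM times 3.37, which is the least-squares slope through the origin of soluble on pellet FPKM over the 82 spike-ins. The largest departure from that product was 1.4e-05 percent.

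The table had 30687 lines, of which 1945 repeated an identifier with identical values and were dropped. In 1889 lines the gene name stood in the RNA type column, and the line with a true type was kept wherever there was a choice. This left 28742 identifiers, 28660 without the spike-ins. Of 27812 Ensembl identifiers, 27475 were matched to a symbol after removing the version. The summed FPKM was 956598 in the soluble fraction and 834872 in the pellet. No locus was listed at 0 in either fraction. FPKM keeps no read counts, so the depth of the libraries is unknown, and no interval based on counts is given for any expression value. Coordinates are those of the table, in mm10. Its starts count from 0, as shown by all 82 spike-ins starting at 0, and 1 was added to each. A locus in the table spans all genes that were assembled together, so overlapping genes can carry the same coordinates. Such sharing applied to 6055 of the tested loci (43.5%), and how fragments were divided between overlapping genes is not given in the sources used here. Gene spans came from RefSeq on GRCm38.p6, the same build as mm10.

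The fold of a locus is the log2 of pellet FPKM times the spike-in factor over soluble FPKM, called the spike-in scale. It was recomputed here from the FPKM columns. A positive value means more RNA in the pellet relative to the spike-ins, and reading it as more RNA in that fraction assumes equal spike-in amounts in both. On the FPKM scale, without the factor, every log2 value is lower by 1.75. Both scalings are deposited, and the choice of the spike-in scale for the leading values was made once the columns were known, because the deposited enrichment uses it. Loci with a mean of both FPKM values of at least 0.5 were tested, 13917 in all, and a locus was counted as higher or lower in the pellet at a difference of at least 2-fold. No pseudocount was added, since no value was 0.

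Because each fraction has a single pooled value, the spread between replicates cannot be computed, no p-value was computed for any locus or list, and the folds carry no replicate error. The limma fit, the Fisher test and the permutation p planned before the data were examined were therefore replaced by counts, Wilson intervals and percentiles. The error that the table does allow is the scatter of the spike-ins about the common factor, which covers library preparation, sequencing and quantification of pooled values but not the fractionation or the cells. Gene lists were fixed before the data were examined. For each list with at least 5 tested members, the median log2 fold was placed among 10000 random lists of the same size drawn from tested loci within 20 bins of mean FPKM. A percentile describes this table and is not a test across replicates. Lists of protein-coding genes were also matched on gene span in 5 bins, with the 20 bins of mean FPKM merged into 5. RNA types are those of the table. The level around noncoding loci was taken from the nearest gene with a symbol within 100 kb, and its difference was set against 10000 shuffles.

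The genes named were set by rules fixed before the data were examined. They are the 10 loci with a symbol and the largest fold each way, with a mean of at least 1 FPKM. Added to these are up to 2 members of every list with at least 5 tested members that differ by 2-fold or more, each way, and the 5 loci without a symbol with the largest fold each way. Malat1, Neat1, Xist, Kcnq1ot1, Meg3, Gapdh, Actb, Myh6, Nppa, Gata4, Tbx5 and Nkx2-5 were named whatever their values. Malat1, Neat1 and Actb were not analysed here. A gene that these rules select is not reported here. RNAs shorter than 200 nucleotides with a symbol are described as groups. Other names were chosen after their values were seen, and are marked so.

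Alternatives covered the pseudocount (0.01, 0.1 and 1), the filter on low values, the scaling, the fold threshold, loci with a symbol, small RNA types and overlapping loci. The method was checked on simulated data for the 13917 tested loci, with noise of the size of the spike-in scatter. The 2-fold threshold picked up 0% of 50 loci simulated at 1.5-fold, 54% of 50 at 2-fold and 100% of 50 at 3-fold and at 4-fold, and 0% of the 13717 unchanged ones. Of 200 random lists, 5% fell outside the central 95%. These rates follow largely from the settings, since noise of that size hardly carries an unchanged locus to 2-fold. They do not cover differences between replicates, the fractionation, or the division of overlapping fragments. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.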

Results

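Nuclear RNA of HL-1 cells, a mouse atrial cardiomyocyte line, was measured in a chromatin pellet and in the soluble nuclear extract, with 3 libraries per fraction pooled by the authors into 1 FPKM value per locus. The comparison asks which transcripts stay with chromatin after nuclear fractionation and which are found in the soluble extract. Spike-ins with a mean of at least 0.5 FPKM followed a single factor between the fractions closely. Their log2 residuals had an SD of 0.12 (n = 47 spike-ins) and ranged from -0.28 to 0.23, and 0 of the 47 was off by 2-fold or more. Below that level, 5 of 35 spike-ins were off by 2-fold or more. The SD was 0.37 between 0.05 and 0.5 FPKM (n = 16) and 0.85 below 0.05 FPKM (n = 19). This scatter is technical. There is no replicate value, so no difference below is set against the spread between cultures, and the depth of the libraries is unknown.

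Tbx5-dependent loci, small nucleolar RNAs and several other noncoding types lay towards the chromatin pellet, and messages for the ribosome, the respiratory chain and histones lay towards the soluble fraction on both scales. Of 13917 tested loci, 4434 were at least 2-fold higher in the pellet on the spike-in scale, 1467 at least 2-fold lower, and 8016 lay within 2-fold. Higher loci thus made up 75.1% of those past the threshold, against 13.6% on the FPKM scale, where 1344 were higher and 8514 lower. The median log2 fold of all tested loci moved from 0.41 to -1.34 between these scales. The 1344 higher loci and the 1467 lower loci hold on both scales, which the constant shift of 1.75 between the scales makes necessary. The summed FPKM was concentrated in few loci: the top 10 took 34.9% of it in the soluble fraction and 37.4% in the pellet. Scarna9, a small Cajal body RNA named after its values were seen, alone took 10.2% of the pellet sum.

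**Figure D1:**
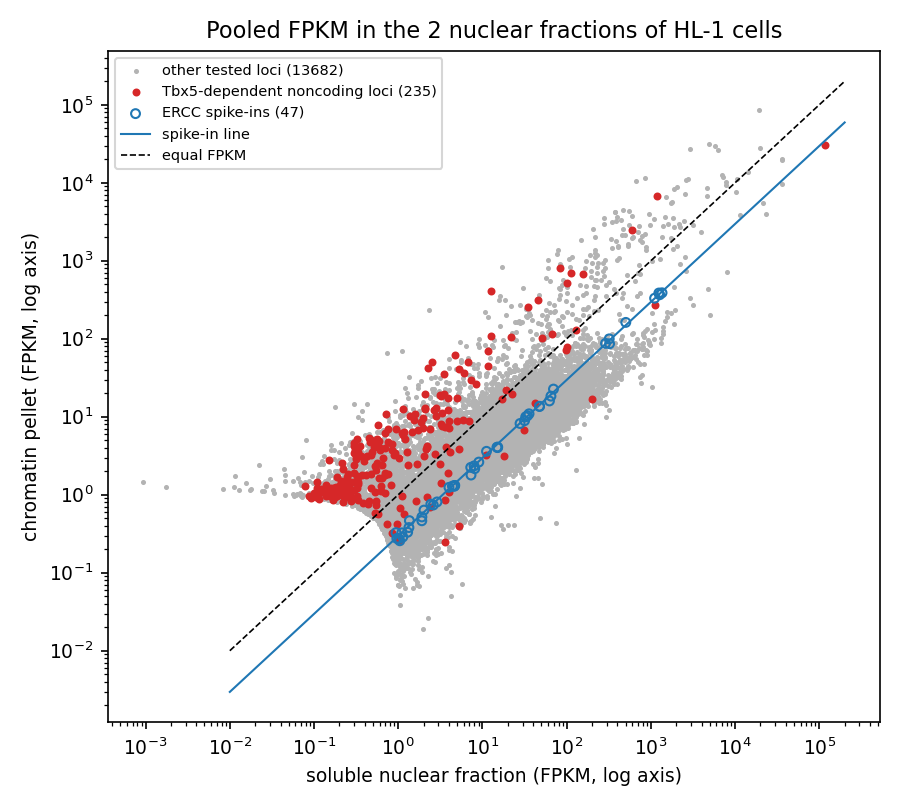
Pooled FPKM of each tested locus in the soluble nuclear fraction (x, log axis) against the chromatin pellet (y, log axis); the solid line is the spike-in factor of 3.37 and the dashed line is equal FPKM. The 47 spike-ins at 0.5 FPKM or more follow the solid line, while most of the 235 Tbx5-dependent noncoding loci lie above both lines.

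Protein-coding genes had a median close to balance on the spike-in scale alone. Of 11397 tested, 2732 were higher in the pellet and 1209 lower, with a median log2 fold of 0.26 (interquartile range -0.43 to 0.97), which turns to -1.49 on the FPKM scale. Long intergenic noncoding RNAs had a median of 1.76, with 249 of 370 higher and 8 lower. On the FPKM scale it was 0.00, with 111 higher and 100 lower. Antisense RNAs had a median of 1.30, with 138 of 236 higher and 13 lower, but -0.45 with 63 higher and 87 lower on the FPKM scale. Among antisense loci with a mean of at least 5 FPKM the spike-in median was -0.25. Processed transcripts, with 121 of 192 higher and 6 lower, likewise had a median of 1.48. It became -0.28 on the FPKM scale, with 55 higher and 61 lower. Sense intronic RNAs lay strongly towards the pellet, with 25 of 26 higher, 0 lower and a median of 3.92, or 2.16 on the FPKM scale. Unclassified loci awaiting experimental evidence (the type TEC) had 189 of 212 higher, 0 lower and a median of 3.83, or 2.08 on the FPKM scale. Whether the signal of sense intronic and TEC loci is unspliced RNA of the genes around them was not tested. The medians of long intergenic, TEC and sense intronic RNAs lay at the 100th percentile of level-matched random lists, and that of antisense RNAs at the 99.9th.

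Small nucleolar RNAs, the guides of ribosomal RNA modification, dominated the pellet. They held 62.8% of its summed FPKM but 17.6% of the soluble sum, and 288 of 312 were higher in the pellet against 5 lower, with a median log2 fold of 3.38 (1.63 on the FPKM scale). Snord17 (log2 fold 5.38, from 203.6 soluble to 2516 pellet FPKM) and Rnu3a, a U3 RNA of early ribosomal RNA processing (3.89, from 1905 to 8350 FPKM), had the largest folds among those of at least 200 nucleotides. Small nuclear RNAs had a median of 2.47, with 138 of 168 higher and 2 lower, but 0.71 with 69 higher and 20 lower on the FPKM scale. MicroRNA loci had a median of 1.92, with 73 of 108 higher and 12 lower, but 0.16 with 42 higher and 34 lower on the FPKM scale. Miscellaneous RNAs had 3.60, with 52 of 71 higher and 6 lower, or 42 and 17 on the FPKM scale. The list of small structured RNAs, largely the small nucleolar RNAs already counted, had 102 of 113 higher and 2 lower, with a median at the 100th percentile. Mitochondrial transfer RNAs, similarly short, went the other way: 0 of 13 were higher, 7 were lower, and the median was -1.13. FPKM of RNAs shorter than the sequenced fragments depends on an effective length that is poorly determined, which touches both fractions.

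**Figure D2:**
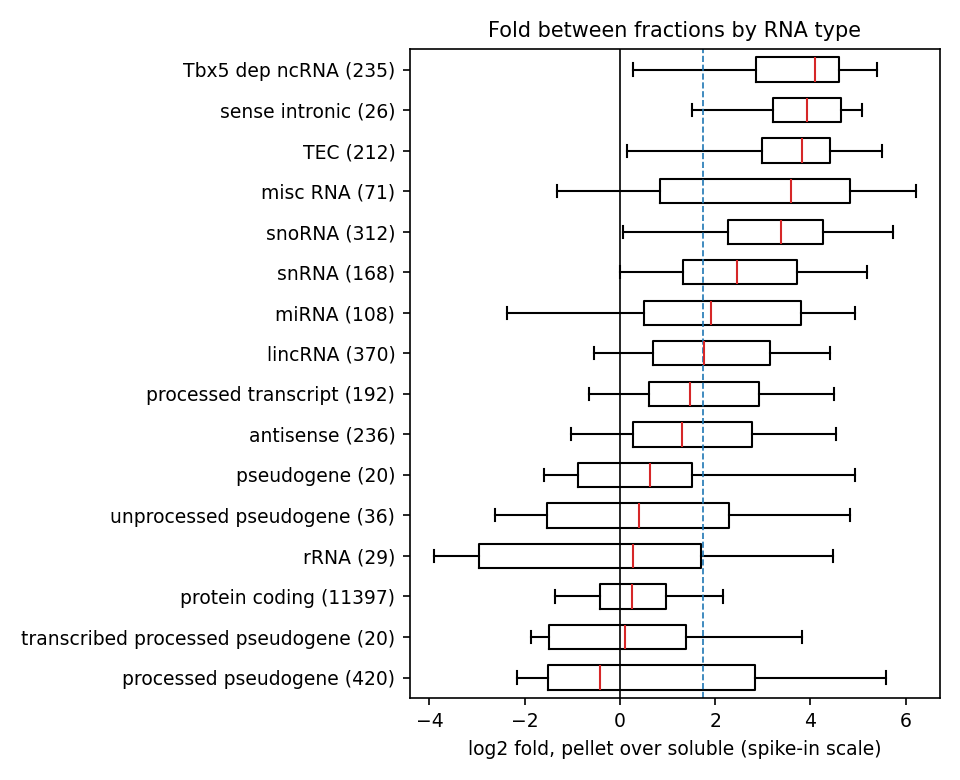
Log2 fold of pellet over soluble on the spike-in scale by RNA type for types with at least 20 tested loci, with the number of loci in brackets; boxes span the quartiles, red lines are medians, whiskers run from the 5th to the 95th percentile, and the dashed line at 1.75 marks equal FPKM. Tbx5-dependent loci (median 4.09) stand highest and processed pseudogenes (median -0.42) lowest.

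The loci that the table types as Tbx5-dependent noncoding RNA had the highest median pellet fold of the RNA types, though the share of loci higher in the pellet was larger for sense intronic RNAs (96.2%) and small nucleolar RNAs (92.3%). Tbx5 is a T-box transcription factor of atrial and conduction system development. Of 849 such loci, 235 passed the level filter, none with a gene symbol, and 214 of these (91.1%) were at least 2-fold higher in the pellet while 3 were lower. Their median log2 fold was 4.09 (interquartile range 2.86 to 4.60), equal to 17.0-fold, and it stayed at 2.33 on the FPKM scale. Random lists of tested loci at their level had medians between 0.51 and 0.96, and lists drawn from these loci and long intergenic RNAs together lay between 2.37 and 3.24. How the loci were selected is not given in the sources used here, so whether this set is independent of the present libraries is not known.

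Pellet association of these loci was similar inside and outside genes and across lengths. The 137 tested loci outside all RefSeq spans had a median of 4.09, with 130 higher and 0 lower, and the 98 inside had 4.03, with 84 higher and 3 lower. The 103 loci under 200 bp had a median of 3.89, and the 87 of at least 1000 bp had 4.27. Over all 849 loci, including those with too little signal to be tested, 794 were higher and 4 were lower.

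Every tested locus without a symbol belonged to this class. Of these, XLOC_061514 (chromosome X, 150460178 to 150460243, overlapping Apex2, a base excision repair endonuclease) had 12.5 FPKM in the soluble fraction and 406.7 in the pellet, the largest log2 fold at 6.77. XLOC_040248 (chromosome 4, 82265690 to 82265788) followed at 6.07. XLOC_050197 (chromosome 7, 128016340 to 128016440, 4947 bp from Trim72) had a log2 fold of 5.97. XLOC_056175 (chromosome 9, 22944130 to 22944295, 55847 bp from Bbs9) had 5.96, and XLOC_024344 (chromosome 17, 29244519 to 29244654, 6181 bp from Ppil1) had 5.77. The 3 lower in the pellet were XLOC_021104 on chromosome 16 (-2.12), XLOC_008866 on chromosome 11 (-1.98) and XLOC_015381 on chromosome 13 (-1.79). The class also held the largest FPKM of the soluble fraction. XLOC_041511, named after its values were seen, had 116696 FPKM, 12.2% of the soluble sum, with a log2 fold of -0.16. It is a 109 bp locus on chromosome 5, from 17776727 to 17776835. Like it, the loci named here with the largest folds towards the pellet span under 200 bp. As for the small RNAs, FPKM of such short loci depends on a poorly determined effective length.

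Among the 13917 tested loci, those without a symbol were the same 235, so their counts restate those of the class. They made up 214 of 4434 loci higher in the pellet (4.83%, 95% Wilson interval 4.23 to 5.50) and 3 of 1467 lower ones (0.204%, 0.0696 to 0.60). The interval covers counting of loci only and treats them as independent, although many Tbx5-dependent loci come in runs along a chromosome. On the FPKM scale the shares were 13.4% and 0.223%. The genes nearest to chromatin-enriched loci within 100 kb, 135 in number, had a median total signal of 19.9, against 5.64 for the 19 genes nearest to loci that were not enriched and 3.19 for all genes with a symbol. The difference between the first 2 groups was 1.82 on the log2 scale and lay at the 90.4th percentile of shuffles, inside their central 95%. Against random sets of 135 genes with a symbol, the median of the first group lay at the 100th percentile. Those sets came from all genes with a symbol, whatever their level. Tested protein-coding genes had a median of 12.9 FPKM in the soluble fraction alone. The percentile therefore does not show that the neighbours stand above expressed genes. Overlap of the enriched locus with the gene itself was recorded in 56 cases.

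A list of annotated long noncoding RNAs, drawn up for action at chromatin but also holding microRNA hosts, lay towards the pellet. Of its 8 tested members, 7 were higher in the pellet and 0 lower, with a median log2 fold of 3.70 (1.95 on the FPKM scale, 100th percentile). Airn, the antisense RNA that silences Igf2r in cis (ENSMUSG00000078247.3, chromosome 17), had 7.66 FPKM in the soluble fraction and 46.9 in the pellet, a log2 fold of 4.37. Mir17hg, host of the miR-17 cluster, had 4.41. Xist (2.71), Kcnq1ot1 (5.37) and Meg3 (3.92) were below 0.5 FPKM, where the spike-in SD was 0.37 or more, and were not tested. Kcnq1ot1 is a long antisense RNA of an imprinted domain. Its values were 0.0126 and 0.154 FPKM.

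Cardiac long noncoding RNAs had a median of 2.12, with 4 of 7 higher and 0 lower (98.4th percentile, and 0.37 on the FPKM scale). Mir143hg, the host transcript of the smooth muscle microRNAs miR-143 and miR-145 (chromosome 18), reached 53.5 FPKM in the pellet with a log2 fold of 5.02. Gm21747, now named Mir133a-1hg as host of the muscle microRNA miR-133a-1, also had 5.02. A list drawn up for host transcripts of small nucleolar RNAs had 10 of 18 higher, 0 lower and a median of 1.12. That median turns to -0.64 on the FPKM scale. Snhg1 was highest at 3.57, followed by Mir22hg, by its name a microRNA host, at 2.92.

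Messages for the respiratory chain and the ribosome were depleted from the pellet. Of 76 nuclear genes of oxidative phosphorylation, 65 were at least 2-fold lower and 0 higher, with a median log2 fold of -1.57. Uqcrq, a subunit of complex III, had -2.39 (262.5 soluble and 14.9 pellet FPKM), and Atp5e, of the ATP synthase, had -2.04. Of 79 ribosomal protein genes, 70 were lower and 0 higher, with a median of -1.52. Rps16 had -2.45 and Rps26 -2.11. Transcripts of the mitochondrial genome had a median of -1.74, with 15 of 21 lower and 0 higher. The complex I gene mt-Nd4 (319.6 soluble and 12.1 pellet FPKM) had -2.97 and mt-Nd5 -2.77. All 3 medians were at the 0th percentile of level-matched lists.

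Histone genes were strongly soluble, with 42 of 46 lower, 1 higher and a median of -1.79. Hist2h2aa2 had -4.67 at 2.25 FPKM in the soluble fraction, Hist1h4b had -2.48, and Hist1h2ad was the exception at 2.21. Hist2h2aa2 has near-identical copies, between which fragments can be misassigned. Housekeeping messages had 15 of 19 lower and 0 higher, with a median of -1.33 (percentile 0.285, but 5.70 among protein-coding genes matched on span). Tmsb4x, encoding the actin-sequestering peptide thymosin beta 4, had -1.99 and B2m -1.92. Gapdh was within 2-fold at -0.76, with 183.4 soluble and 32.1 pellet FPKM.

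Zinc finger genes of the Zfp-numbered series lay towards the pellet as a family on the spike-in scale. Of 302 tested, 178 were higher and 3 lower, with a median of 1.25 at the 100th percentile. On the FPKM scale the median turns to -0.50, with 12 higher and 85 lower. Zfp457 (3.86) and Zfp607 (3.77) were highest. Zfp428 had -1.26, and Zfp791 (chromosome 8, 47.8 soluble and 0.508 pellet FPKM) had the lowest log2 fold of all tested loci named here, -4.80.

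Splicing regulators and other genes known for introns that are retained in the nucleus showed 18 of 30 higher and 0 lower on the spike-in scale. Their median there was 1.35 (100th percentile). It turns to -0.40 on the FPKM scale, with 6 higher and 9 lower. Ogt, the O-GlcNAc transferase, had 3.44 (17.3 soluble and 55.5 pellet FPKM) and Clk4, a kinase of SR proteins, had 3.05. Both stayed above 1 on the FPKM scale, at 1.68 and 1.30. Immediate early genes lay mostly within 2-fold on the spike-in scale, with 6 of 27 higher, 0 lower and a median of 0.23. On the FPKM scale the median was -1.53, with 1 higher and 18 lower. Fosb stood apart at 4.11 (0.451 soluble and 2.32 pellet FPKM). Atf3 had 1.39, or -0.37 on the FPKM scale. Cell cycle genes had 3 of 29 higher and 0 lower, with a median of -0.12, but 0 higher and 25 lower on the FPKM scale. Both Cenpe (1.53) and the proliferation marker Mki67 (1.30) reversed on the FPKM scale, to -0.22 and -0.45.

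**Figure D3:**
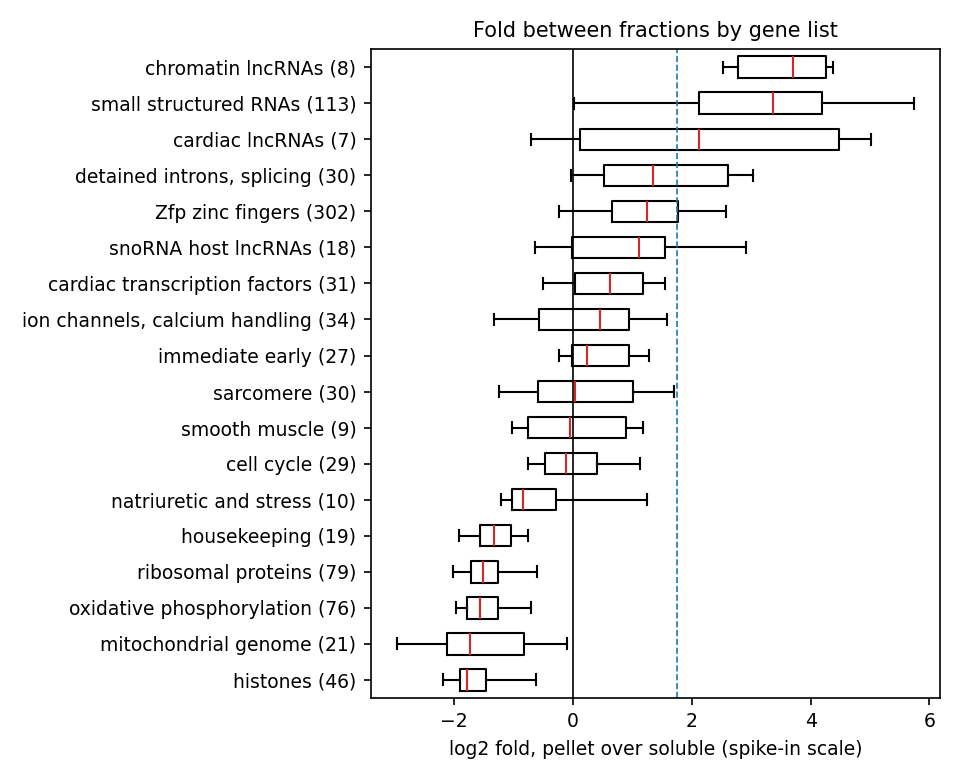
Log2 fold of pellet over soluble on the spike-in scale for the gene lists with at least 5 tested members, with their number in brackets; boxes, lines and whiskers are as for the RNA types, and the dashed line at 1.75 marks equal FPKM. Chromatin lncRNAs (median 3.70) stand at the top and histones (median -1.79) at the bottom.

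Cardiac transcription factors had no clear side. Of 31 tested, 11 were higher and 0 lower, with a median of 0.62, but 0 higher and 16 lower on the FPKM scale, with -1.14. The spike-in median lay at percentile 96.0 of level-matched lists, inside their central 95%, at 98.5 among protein-coding genes alone and at 86.2 with gene span also matched. Meis2 (2.09) and Foxp1 (1.63) had the largest folds, and Foxp1 turns to -0.13 on the FPKM scale. The core factors were within 2-fold: Tbx5 had 0.86 (17.8 soluble and 9.54 pellet FPKM), Gata4 had 0.62 and Nkx2-5 had -0.51, and all 3 are below 0 on the FPKM scale.

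Sarcomere genes split by member on the spike-in scale, with 8 of 30 higher, 5 lower and a median of 0.03. On the FPKM scale the median turns to -1.72, with 0 higher and 20 lower. Actn2, the Z-disc alpha-actinin, had 2.02. The atrial light chain gene Myl7 had -1.34 at 1119 soluble FPKM, and the small heat shock protein gene Cryab had -1.61. Myh6, the alpha myosin heavy chain, had 1.24 (124.4 soluble and 87.3 pellet FPKM), which turns to -0.51 on the FPKM scale. Ion channel and calcium handling genes had 8 of 34 higher and 4 lower, with a median of 0.46. It turns to -1.30 on the FPKM scale, with 1 higher and 23 lower. The inositol trisphosphate receptor gene Itpr2 had 3.04 and the calcium channel gene Cacna1d 2.09, while Sln, encoding sarcolipin, had -1.55 and Hrc -1.43. The sarcomere and ion channel medians lay at percentiles 36.2 and 57.0.

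Natriuretic peptide and stress genes lay towards the soluble fraction, with 3 of 10 lower, 2 higher and a median of -0.85 at percentile 0.09, which became 8.78 among protein-coding genes matched on span. Nppa, encoding atrial natriuretic peptide, had -1.21 at only 1.63 soluble FPKM, and the heat shock gene Hspb1 had -1.39. Ankrd1 went the other way at 1.24, or -0.51 on the FPKM scale. Nppa shares its coordinates in the table with another locus, so its values can depend on how overlapping fragments were divided.

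Markers of other cell types showed no common direction. Of 9 smooth muscle markers tested, several of which cardiomyocytes share, 2 were higher (Synpo2 at 1.91 and Myocd at 1.18) and 2 lower (Cnn1 at -1.29 and Acta2 at -1.03), with a median of -0.05 at the 48.9th percentile; Myocd turns to -0.57 on the FPKM scale. Few markers of the remaining types reached 0.5 FPKM: 4 of fibroblasts, 4 of endothelium, 3 of skeletal muscle, 2 of neurons and 1 of immune cells. Their medians were -0.41, 0.36, -0.73, 1.06 and 1.43 in that order, and all are below 0 on the FPKM scale.

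Among annotated loci with the largest folds towards the pellet, most were noncoding or pseudogenes inside larger loci. Gm12940, a processed transcript on chromosome 4 from 127021324 to 127061152, led with a log2 fold of 8.23 (0.737 soluble and 65.5 pellet FPKM). The processed pseudogenes Gm17228 (7.76), Gm14239 (7.35), Gm29487 (6.21) and Gm15077 (6.19) followed, together with the TEC loci RP24-271M20.4 (6.53), RP23-216O10.6 (6.44), CH25-309J2.1 (6.38) and another on chromosome 9 from 34485894 to 35036716 (6.23). Pcdhgb5, of the clustered gamma protocadherins on chromosome 18, was the protein-coding gene among the 10, at 6.33. Towards the soluble fraction, Zfp791 and Hist2h2aa2 were followed by the pseudogene Gm15531 (-4.60), Alox5ap, encoding the 5-lipoxygenase activating protein (-4.57), and Cntf, encoding ciliary neurotrophic factor (-3.26). Gm6404 (-3.24), mt-Nd4, RP23-407E2.30 (-2.93), Gm6733 (-2.89) and Gm4076 (-2.87) completed the 10. Of these 20 loci, 16 share coordinates with other genes, so part of their fold can depend on how overlapping fragments were assigned. Many of the folds also rest on a value near the floor in 1 fraction. Soluble FPKM was 0.0796 for Gm17228 and 0.0435 for Gm14239, and pellet FPKM was 0.0261 for Hist2h2aa2 and 0.051 for Gm15531. Such loci passed the filter on the mean through the other fraction, and their exact fold is uncertain.

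Long genes were more pellet-associated than short ones. Among 11130 protein-coding genes with a RefSeq span (97.7% of those tested), Spearman's rho between span and log2 fold was 0.45 across genes, which are not independent replicates. Genes higher in the pellet had a median span of 46728 bp and genes lower in it 6520 bp. The median log2 fold went from -0.69 for 1212 genes under 5 kb to 1.19 for 497 genes over 200 kb. Each of these medians is below 0 on the FPKM scale, with the order kept. Across all 13917 tested loci and the extents given in the table, rho was 0.24, or 0.0995 without the filter on low values.

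**Figure D4:**
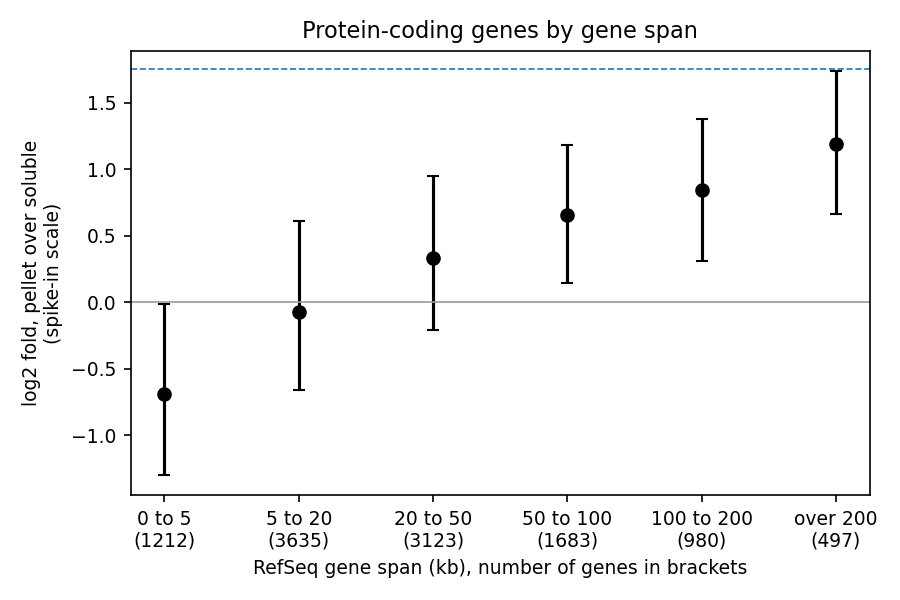
Median log2 fold of pellet over soluble on the spike-in scale (points, with bars from the lower to the upper quartile) for protein-coding genes by RefSeq span in kb; the dashed line at 1.75 marks equal FPKM. Medians go from -0.69 under 5 kb to 1.19 over 200 kb.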

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

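No paired analysis was possible because each fraction has 1 pooled value per locus. For the same reason the replicate block, leaving out libraries, the limma settings, adjusted p thresholds, camera and fry, a test by the authors, and the count-based tools and filters were not run. The overlap, small RNA, median spike-in ratio, fold threshold, protein-coding and span settings were chosen after seeing the data. Depth is unknown, so low loci rest on the spike-in scatter alone.

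The counts of 4434 higher and 1467 lower loci kept within 1.5 times under every pseudocount, with the median spike-in ratio, with symbols only and without small RNAs. They were 14261 and 2546 without a filter, and 2055 higher at a mean of at least 5. Median centring gave 3152 higher and 2652 lower, quantile normalization 2729 and 3272, and the FPKM scale 1344 and 8514. Without overlapping loci there were 2129 and 967, from fewer loci tested. At 4-fold there were 2052 and 125, and at 1.5-fold 2658 were lower. Lists above the central 95% of random lists numbered 6, and 5 with pseudocount 1, at a mean of at least 5 or with quantile normalization. Below it there were 6. Without overlapping loci there were 3 above, where the long noncoding lists have under 5 members, and 5 below, with housekeeping genes at percentile 2.525. With protein-coding members alone there were 3 above, as the noncoding lists drop out and cardiac transcription factors come in. With span also matched there were 2 above and 2 below. Histones and the mitochondrial genome then lack spans, while housekeeping and stress genes lose their place through the matching.

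The FPKM scale reversed Foxp1 (-0.13), Atf3 (-0.37), Ankrd1 (-0.51), Cenpe (-0.22), Mki67 (-0.45), Myocd (-0.57) and Myh6 (-0.51). It also reversed the medians of snoRNA hosts (-0.64), Zfp genes (-0.50), splicing genes (-0.40), antisense RNAs (-0.45) and processed transcripts (-0.28), by the constant shift alone. Antisense RNAs also reversed at a mean of at least 5 (-0.25), where the cause was not tested.

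The share of loci without a symbol among higher ones was 5.56% without a filter, 2.82% at a mean of at least 5, 6.63% with centring, 7.55% with quantiles, 13.4% on the FPKM scale, 5.53% without small RNAs, 8.64% without overlaps, 9.75% at 4-fold and 3.57% at 1.5-fold. Among lower ones it was 0.80% at 4-fold. The Spearman correlation of length with fold was 0.0995 without a filter, 0.357 at a mean of at least 5, and 0.387 (table) or 0.450 (RefSeq) for protein-coding genes. The neighbour difference was 1.49 within 10 kb, 1.497 within 1000 kb and 2.33 without a filter. The cause of these moves was not tested.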

Other observations

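Several Tbx5-dependent loci lie in or beside genes of the cardiac lists. These loci were picked out after their values were seen. Within 100 kb, 28 of the 849 loci have a cardiac transcription factor, sarcomere or ion channel gene of the fixed lists as their nearest gene, and they belong to 10 genes. Gata6 has 11 of them, spread from 10953496 to 11148112 on chromosome 18, with log2 folds between 4.29 and 5.79, while the Gata6 message itself has 0.62. Kcnj3, an atrial potassium channel gene, has 6, with folds between 1.11 and 4.02. Of these, XLOC_032085, XLOC_032086 and XLOC_032088 share the same extent and overlap the gene. All 28 are at least 2-fold higher in the pellet on the spike-in scale and exceed the fold of the neighbouring gene, but only 3 reach 0.5 FPKM. The 3 at 0.5 FPKM or more are XLOC_014150, which overlaps Nr2f1 (5.21, with 5.14 pellet FPKM), XLOC_025364 near Gata6 (4.997, with 1.32) and XLOC_058428 near the pacemaker channel gene Hcn4 (4.14, with 523.7). The last is short, from 58867113 to 58867175 on chromosome 9, and lies 3938 bp from the gene. Its FPKM therefore depends on a poorly determined effective length. On the FPKM scale the lowest of the Kcnj3 loci turns to -0.64.

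The Tbx5-dependent loci also come in runs. A single megabase of chromosome 2, between 45239244 and 45547727, holds 40 of them with a median log2 fold of 4.38, and chromosome 4 has 34 between 85205126 and 85989808 with 4.78. Chromosome 1 has 31 between 161176936 and 161694557 with 4.56. In each of these runs all loci are at least 2-fold higher in the pellet, but 0 of the 40 on chromosome 2 pass the level filter, against 15 of the 34 and 15 of the 31. Whether neighbouring loci are pieces of the same longer transcript was not tested. Among protein-coding genes with a mean of at least 1 FPKM, the gamma protocadherins Pcdhgb5 (6.33), PCDHGA9 (6.05) and PCDHGB6 (5.81) have the 3 largest folds towards the pellet. They share the extent 36930184 to 37841873 on chromosome 18, and the noncoding RP23-407E2.30 of the same extent goes the opposite way at -2.93.

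In the paragraphs that follow, the test of the scaling for Tbx5-dependent loci and all tests for small nucleolar RNAs were chosen after the result was seen. For the Tbx5-dependent loci, low expression alone is argued against, since their median lies at the 100th percentile of lists drawn at the same level. Those lists mixed all RNA types, and TEC loci, at a median of 0.38 soluble FPKM, had a median log2 fold of 3.83. The percentile thus does not set Tbx5-dependent loci apart from other low-level types such as TEC. Unprocessed RNA of overlapping genes is argued against too, because loci outside every RefSeq span have a median of 4.09 with a lower quartile of 3.12. The spike-in factor is not the whole source either, as the median without it is 2.33 and the lower quartile 1.11. That these RNAs are held at chromatin is a hypothesis. Selection of the loci by the authors on chromatin signal was not tested and remains open.

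For the low pellet level of oxidative phosphorylation and ribosomal protein genes, high expression and short gene span were weighed. Against protein-coding lists at the same level, both medians lie at the 0th percentile (0 and 0). With span matched as well, they again lie at 0 and 0, where random lists had medians from -1.12 to -0.66 and from -1.34 to -0.98. Matching on span brings the random median for ribosomal genes from -0.92 to -1.19, against -1.52 observed, so span could account for part of the difference. Whether it accounts for the rest cannot be told from 5 span bins within 5 level bins. The ribosomal genes have a median span of 3.18 kb, and folds change steeply among short genes (median -0.69 under 5 kb and -0.08 at 5 to 20 kb). Transcripts of the mitochondrial genome, which are made outside the nucleus, had a median of 390.6 FPKM in the soluble extract and 39.6 in the pellet (21 tested). RNA from outside the nucleus was therefore present in both fractions. How much of the oxidative phosphorylation and ribosomal protein messages was cytoplasmic carry-over was not separated from nuclear RNA and remains open.

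For small nucleolar RNAs, signal from unspliced host genes is argued against for the 30 outside other genes, with a median of 3.31 and a lower quartile of 1.60. For the other 282 it stays open: taking the highest pellet FPKM of an overlapping gene from theirs lowers the median from 3.38 to 2.94 and the lower quartile from 2.34 to 1.38, under 1 above the median of all tested loci. Short length was weighed within the mitochondrial genome, where 13 transfer RNAs exceed the 8 protein-coding genes by 0.94 in median log2 fold, against the 2.97 by which small nucleolar RNAs exceed all tested loci. Within that genome, short length thus went with a smaller gap. How length acts on nuclear RNAs cannot be told from it, since these are organelle RNAs whose genes have very uneven values (soluble FPKM 1.10 for mt-Co3 and 786.6 for mt-Cytb). Residence in nucleoli that sediment with chromatin is a candidate explanation that these data do not address.

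Processed pseudogenes were split, with 144 of 420 higher and 156 lower in the pellet on the spike-in scale, but 108 higher and 270 lower on the FPKM scale. The 166 inside a locus shared with a protein-coding gene had a median of 1.33, and the 240 in a locus of their own had -0.75, a difference of 2.08. Both medians are below 0 on the FPKM scale, while the difference does not depend on the scale. This is consistent with the higher values in shared loci coming from unspliced RNA of the gene around them, while mismapped messages of the parent genes were not examined.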
